A study of Homo sapiens with 6 samples.

How the data were processed

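RNA was sequenced from human bone marrow mesenchymal stem cells, commercial primary cells from 3 donors. Cells of each donor were grown for 48 hours without or with 10 ng/ml of platelet-derived growth factor BB (PDGF-BB), and the control and treated cells came from separate plates collected together, per the labels. This gave 6 libraries, 3 control and 3 PDGF-BB, with 1 library per donor and condition. Per the labels' protocols, total RNA was purified with a Qiagen RNeasy kit and libraries were made with a KAPA mRNA HyperPrep kit.

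The deposited table held whole-number read counts per gene, not normalized, with Ensembl gene identifiers, gene types and hg38 exon coordinates, per the file headers. The submitters' processing notes name bcl2fastq, the aligner STAR 2.5.3a, featureCounts of Subread 2.0.1 and edgeR 3.38.4 on the hg38 genome build. The annotation and the strand setting of the counter are not given in the sources used here. Without them, reads on exons shared by overlapping genes cannot be assigned with certainty. Exons of 14 of the 118 named genes overlap another gene in the table, and in 8 of these the partner holds at least 10% of the named gene's own reads. These 8 are TTN, BMP6, ADIRF, PRG4, CXCL16, LEPR, ITGA1 and ITGB2, whose values are uncertain to that extent.

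The table had 26485 rows. In 2031 of them no gene was named, and these rows, with 0.268% to 0.303% of each library's counts, were left out of library sizes and tests. Of the 24454 named genes, 14415 passed edgeR's filterByExpr with the treatment groups and 10039 did not. XIST and Y-linked genes stayed in the fits and their counts of calls but were left out of every gene table, and 7 of the paired calls were among them. Total counts per library ran from 32811079 to 49610880. The libraries were compared for duplicates, and the smallest chi-square per degree of freedom between any 2 libraries was 68.1, far above sampling noise. Levels are given as CPM, each count relative to its library's total after TMM scaling, as mean ± SD over 3 donors.

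The comparison of PDGF-BB with control was fitted in edgeR 4.0.16 under R 4.3.3, with TMM factors and the robust quasi-likelihood F test (glmQLFit, glmQLFTest). P values were adjusted by the Benjamini-Hochberg method and called under 0.05. The design, gene lists, rule for named genes and most other settings were chosen before the data were examined. Some genes picked by that rule are not reported here. The model chosen first held the treatment alone, and the model with the donor as a block was fixed beside it. Control and treated libraries of a number came from the same donor by the labels, so the numbers paired the samples. The number of the third donor differs in 1 digit between the sample titles and the table's columns, and was taken to mean the same donor because the other donors match. Deviations from the group means correlated at 0.665, 0.784 and 0.754 across genes within the 3 donors, and from -0.506 to -0.185 between libraries of different donors. The block lowered the biological coefficient of variation from 32.2% to 12.6%. "Rose", "fell" and "changed" refer to this paired test throughout, with its log2 fold change of PDGF-BB over control. The standard error (SE) of a fold change is approximate, the change divided by the square root of its F value. The difference between donors was tested on the donor terms of the paired model.

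The 30 gene lists, with 759 entries in all, were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2. Camera used a preset correlation of 0.01, and was repeated with an estimated correlation, with fry, and with the donor block. All 759 entries matched a gene of the table, 6 of them through the Ensembl identifier because the table used older symbols (CTGF for CCN2 and CYR61 for CCN1, for example). Counts of members past the threshold are given over all genes tested and adjusted over the list alone. Named genes were PDGFRA, PDGFRB, PDGFA and PDGFB, the 12 protein-coding genes with the largest and the 12 with the smallest change among those past the threshold, and up to 2 members per direction and list with the smallest p. The 24 had a mean log2 CPM of at least 1 and the same direction in all 3 donors. As no gene passed without the block, all of these came from the paired test. Any other gene given a value was chosen after its values were seen.

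The alternatives were DESeq2 1.42.0 and limma-voom, each with and without the block, other scalings, other filters, a test against a 1.5-fold change, thinning to equal totals, and leaving out libraries or donors. Both models were tested on simulated counts for this comparison, with 200 changed genes and the library sizes of the real libraries. The means were those of each donor over its control and PDGF-BB libraries, and each changed gene had the same fold in every donor. In the real comparison far more genes were called and changes differed between donors, so the shares below may not carry over to it. With a spread set by expression level (14253 genes), the paired test recovered 64.2%, 94% and 100% of genes changed 1.5-fold, 2-fold and 4-fold, with 6 false genes among 178 calls. The unpaired test recovered 0%, 13.4% and 78.8%, with 0 false among 61. With a separate spread for each gene (14248 genes) the paired test recovered 62.7%, 98.5% and 100% but made 38 false calls among 212, and the unpaired test recovered 0%, 10.4% and 72.7% with 0 false among 55.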

Results

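Bone marrow mesenchymal stem cells, stromal cells that can form bone, cartilage and fat, were profiled by RNA sequencing after 48 hours with or without 10 ng/ml PDGF-BB, a mitogen that binds both PDGF receptors. The question was how this growth factor alters the transcriptome of these cells. The control libraries of donors 1, 2 and 3 held 49610880, 47270063 and 49488815 counts, and the PDGF-BB libraries 32811079, 44668212 and 47008805. Between 17702 and 18057 named genes had a read in 5 of the libraries. PDGF-BB replicate 1, the shallowest library, had reads on 19600. FN1, which encodes the matrix protein fibronectin, held 8.99%, 6.03% and 8.61% of the counts in the controls of donors 1, 2 and 3, and 4.89%, 6.02% and 6.30% after PDGF-BB.

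After PDGF-BB, most genes of DNA replication, mitosis and ribosome assembly on the lists rose, as did many of the ERK response and several chemokine and EGF receptor ligand genes. Among genes of the extracellular matrix, of the contractile apparatus, of the ATF4 amino acid response and of cell cycle arrest, many fell and few or none rose. With the preset correlation, the gene set test camera called 12 of the 30 gene lists, 5 higher and 7 lower. With an estimated correlation it called none (smallest adjusted p = 0.353). In the paired edgeR test 1883 genes rose and 1894 fell among 14415 tested, 3777 in all. Of these, 484 rose and 513 fell by at least 2-fold, 3627 were protein-coding, and 3772 moved in the same direction in all 3 donors. Over all tested genes, 63.4% moved in the same direction in the 3 donors, against 25% by chance. The changes of single donors correlated across genes at 0.65, 0.70 and 0.66, where genes are not independent replicates. On average over genes, donors took up 49.3% of the variance of log2 CPM, treatment 34.6% and the rest 16.1%. The donor term has more degrees of freedom than the treatment, so these shares do not show that donors outweighed it.

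Without the donor block edgeR called 0 genes, with 3025 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0862, limma-voom called 0 and DESeq2 called 1543. Every gene called below rests on the paired test, which called 2198 genes without donor 1, 4265 without donor 2 and 0 without donor 3 (3919 at an unadjusted p under 0.05, and 1348 by DESeq2). Scaled by library totals alone, the paired test called 2832 higher and 1315 lower, 68.3% higher against 49.9% with TMM, and the median log2 change of all tested genes was 0.11 against -0.02.

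**Figure D1:**
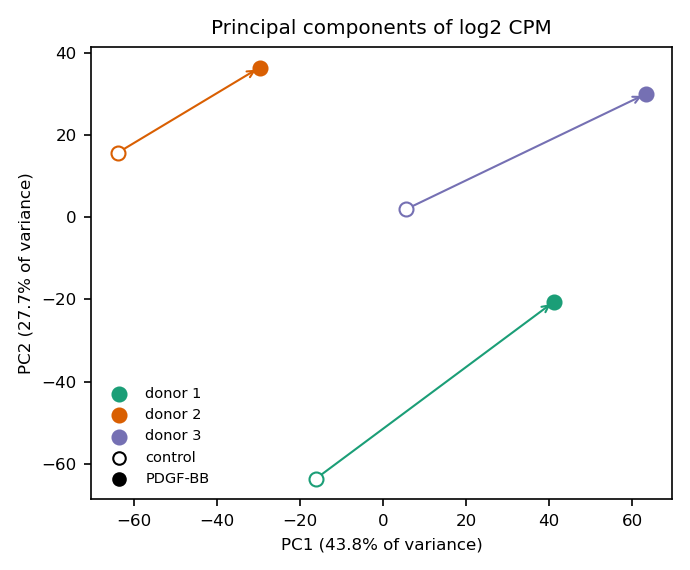
Principal components of log2 CPM of the 6 libraries, PC1 (43.8% of the variance) against PC2 (27.7%), with open circles for control, filled circles for PDGF-BB, a colour per donor, and an arrow from control to PDGF-BB of the same donor. All 3 arrows point to higher PC1 and higher PC2, and donors differ in where they start.

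Of the genes of the treatment's own family, the receptor gene PDGFRB fell while PDGFRA did not pass. PDGFRB (ENSG00000113721.13, hg38 chromosome 5, 150113839 to 150155859) went from 584 ± 89.6 to 333 ± 149 CPM (SD, n = 3), a log2 change of -0.89 (SE 0.17, edgeR paired adjusted p = 0.0169). PDGFRA (ENSG00000134853.11, chromosome 4, 54229097 to 54298245) had 843 ± 285 CPM in control and 911 ± 363 CPM after PDGF-BB, with a log2 change of 0.11 (SE 0.16, edgeR paired adjusted p = 0.645) and donors that moved in different directions. The ligand gene PDGFA had 8.72 ± 0.968 and 6.38 ± 1.19 CPM, lower in all 3 donors but short of the threshold at -0.46 (edgeR paired adjusted p = 0.0562). PDGFB was too scarce to test, with 0 to 4 counts in each library. Of the 6 tested members of the list of PDGF ligands and receptors, 2 fell and 0 rose, or 3 and 0 when adjusted over the list alone, and the other that fell was PDGFD, by 1.84 on the log2 scale (SE 0.33). PDGFD rested on very different donor levels, with 1515 counts in the control of donor 2 against 99 and 133 in those of donors 1 and 3. In camera the list did not pass (adjusted p = 0.183, or 0.147 with the donor block), and without donor 1 the paired test called 1 member, PDGFRB. Camera called the list lower without donor 2 (adjusted p = 0.0277), but not without donor 1 (0.14) or donor 3 (0.642).

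The largest rises were in NTSR1, a neurotensin receptor gene, the EGF receptor ligand gene AREG, the retinol dehydrogenase gene DHRS9 and EREG, which encodes another EGF receptor ligand. NTSR1 (chromosome 20, 62708837 to 62762771) went from 0.219 ± 0.137 to 12.8 ± 14.3 CPM (SD, n = 3), a log2 change of 5.69 (SE 0.38, edgeR paired adjusted p = 0.00209), and its rise ran from 3.11 in donor 2 to 6.31 in donor 1. AREG, which encodes amphiregulin (ENSG00000109321.10, chromosome 4, 74445098 to 74455009), went from 0.348 ± 0.178 to 10.8 ± 4.32 CPM, 30.5-fold (log2 change 4.93, SE 0.25, edgeR paired adjusted p = 0.00175). EREG, the gene of epiregulin, close to AREG on chromosome 4, went from 0.435 ± 0.513 to 7.66 ± 6.12 CPM (log2 change 4.23, SE 0.28, edgeR paired adjusted p = 0.00328). DHRS9 rose by 4.51 (SE 0.25), the RNA-binding protein gene IGF2BP3 by 3.36 (SE 0.26), and the glutamate receptor subunit gene GRIA1 by 2.99 (SE 0.29). The collagenase gene MMP1 rose by 2.95 (SE 0.25), TTN, the gene of titin, by 2.88 (SE 0.36), and PTHLH, the gene of parathyroid hormone-related protein, by 2.86 (SE 0.44). TTN shares exon sequence with its antisense gene. Donors also differed for the potassium channel gene KCNK3 (1.36 to 5.71 in single donors, fitted 3.90, SE 0.80), the carbonic anhydrase gene CA2 (0.89 to 3.99, fitted 2.97, SE 0.71) and the neutrophil chemokine gene CXCL8 (1.87 to 5.76, fitted 3.13, SE 0.63). Without donor 1 the paired test called 11 of these 12 genes, all but CA2 (edgeR adjusted p = 0.366). That fit has 1 residual degree of freedom. It called KCNK3 although donors 2 and 3 changed by 1.36 and 5.71, and without donor 3 the paired test called 0 genes.

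The largest falls included abundant secreted and cytoskeletal genes. CEMIP, which encodes a hyaluronan-degrading protein (chromosome 15, 80779343 to 80951662), went from 1634 ± 1635 to 100.5 ± 15.8 CPM (SD, n = 3), a log2 change of -3.55 (SE 0.56, edgeR paired adjusted p = 0.0150). FLG, the gene of filaggrin, went from 701 ± 597 to 54.1 ± 18.2 CPM (log2 change -3.10, SE 0.69, edgeR paired adjusted p = 0.0330), with changes of -4.12, -1.12 and -3.85 in donors 1, 2 and 3. The fibroblast growth factor receptor gene FGFR2 fell by 3.11 (SE 0.51), and IGF1, the gene of insulin-like growth factor I, by 2.56 (SE 0.47). The muscle-related genes JPH2, LMCD1, LMOD1 and SYNPO2 also fell, with log2 changes of -2.76 (SE 0.27), -2.65 (SE 0.43), -2.63 (SE 0.42) and -2.49 (SE 0.28). OXTR, the oxytocin receptor gene, fell from 13.3 ± 12.6 to 1.90 ± 1.03 CPM. PTGIS, the gene of prostacyclin synthase, NXPH3 and C1orf198 changed by -2.45 (SE 0.50), -2.86 (SE 0.29) and -2.45 (SE 0.29). Without donor 1, 5 of the 12 passed (CEMIP, NXPH3, JPH2, OXTR and C1orf198). All 12 had a negative fitted change in that fit, FLG at -2.49 and FGFR2 at -2.66. Genes were picked only if all 3 donors moved the same way, so these signs were set in advance and add no support.

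**Figure D2:**
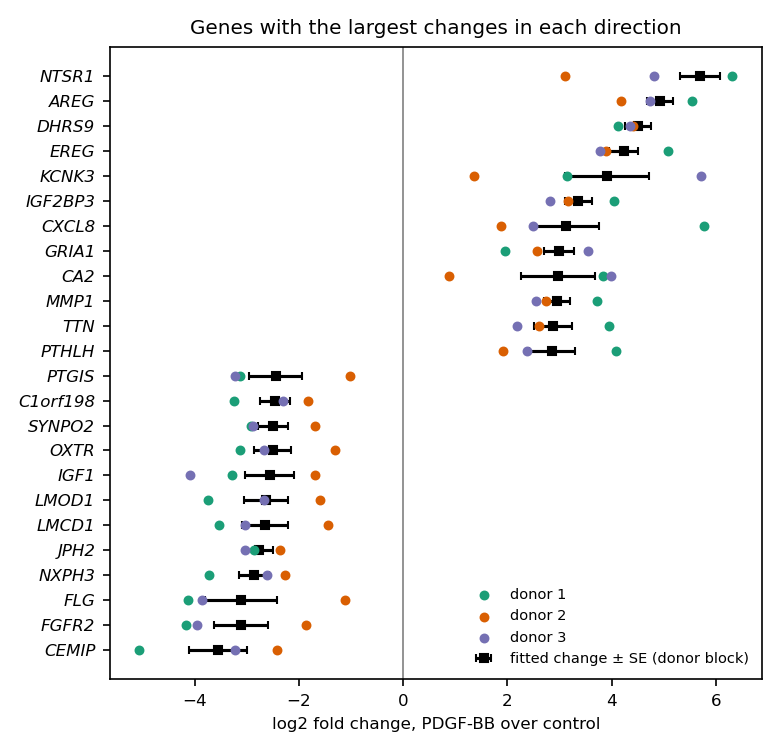
Log2 fold change of PDGF-BB over control for the 12 genes with the largest rises and the 12 with the largest falls, with black squares for the paired edgeR estimate, bars for ± SE and coloured points for the 3 donors. Every point lies on the same side of 0 as its gene's estimate, which the rule that picked these genes required. Donor 2 lies nearest to 0 for all 12 genes that fell, FLG at -1.12 among them.

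Genes of the cell cycle rose together. All 44 tested members of the G2/M list rose, and 36 of 40 members of the G1/S list rose with 0 that fell, with the same counts when adjusted over the list alone. NUF2, a kinetochore protein gene, went from 3.26 ± 1.26 to 11.9 ± 2.91 CPM (SD, n = 3; log2 change 1.90, SE 0.18, edgeR paired adjusted p = 0.00420), and GTSE1, a gene of the G2 and S phases, rose by 1.33 (SE 0.12). EXO1, an exonuclease gene, rose by 1.85 (SE 0.18), and the replicative helicase gene MCM5 by 1.17 (SE 0.10). Without the donor block, 41 members of the G2/M list and 29 of the G1/S list passed when adjusted over the list alone. Ribosome biogenesis genes rose in 22 of 30 cases and fell in 0, or 28 and 0 adjusted over the list alone, with PA2G4 at 0.66 (SE 0.09) and the nucleolar protein gene NOP16 at 0.71 (SE 0.11). Of 21 p53 targets and cell cycle inhibitors, 10 fell and 0 rose, or 13 and 2 adjusted over the list alone. GADD45B, a stress-induced growth arrest gene, fell by 1.38 (SE 0.23) and the p53 target PHLDA3 by 0.49 (SE 0.10). Without donor 1, 44 and 32 genes of the G2/M and G1/S lists and 12 of ribosome biogenesis rose, and 5 inhibitors fell, with GADD45B and not PHLDA3 among them. In camera these 4 lists passed, the G2/M list at an adjusted p of 6.86e-21, G1/S at 4.34e-19, ribosome biogenesis at 2.84e-10 and the inhibitors at 0.000785. Each gave an adjusted p = 0.353 with an estimated correlation.

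Feedback regulators of ERK signalling and immediate early genes formed a single list. Of its 30 members 16 rose and 3 fell, over all genes and adjusted over the list alone alike. SPRED3 and SPRED1, inhibitors of the RAS-ERK pathway, rose by 1.26 (SE 0.10) and 1.03 (SE 0.10), and DUSP6, an ERK phosphatase gene, and SPRY4, a Sprouty inhibitor gene, by 2.12 and 1.95. The AP-1 gene FOSL1 rose by 1.58. The 3 that fell were the AP-1 genes JUND, by 0.88 (SE 0.14), and FOSL2, by 0.53 (SE 0.11), and the stress gene ATF3, by 1.40. FOS (-0.85), EGR1 (0.25), MYC (-0.24) and the feedback genes DUSP1 (-0.06) and SPRY1 (0.62) did not pass. Camera called the list (adjusted p = 0.00148, and adjusted p = 0.353 with an estimated correlation).

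Secreted signals moved both ways. Among 18 tested cytokines and chemokines 8 rose and 2 fell, or 10 and 3 adjusted over the list alone. LIF and IL11, cytokines of the interleukin 6 family, rose by 1.35 (SE 0.11) and 1.21 (SE 0.10), and the 2 that fell were CXCL16 by 0.99 (SE 0.13) and CXCL12, a chemokine that retains blood stem cells in the marrow, by 0.67 (SE 0.18). CXCL16 shares exon sequence with MED11. IL6 itself did not pass (-0.20). Of 25 secreted growth factors 9 rose and 5 fell, with the same counts adjusted over the list alone. AREG and EREG led those that rose. ANGPTL2, which encodes an angiopoietin-like protein, fell by 0.94 (SE 0.11), as did GDF15 by 1.68, FGF7 by 1.54 and FGF2 by 0.76. Camera called the cytokine list (adjusted p = 0.00416, and adjusted p = 0.353 with an estimated correlation) and not the growth factors (adjusted p = 0.393).

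Matrix and contractile genes fell more often than they rose. Of 37 matrix glycoproteins and proteoglycans 23 fell and 2 rose, or 24 and 2 adjusted over the list alone. The 2 that rose were the hyaluronan synthase genes HAS2, from 219 ± 83.3 to 667 ± 280 CPM (SD, n = 3; log2 change 1.58, SE 0.20, edgeR paired adjusted p = 0.00722), and HAS1, by 1.25 (SE 0.15). The small proteoglycan genes FMOD and PODN fell by 1.04 (SE 0.10) and 1.62 (SE 0.16), while FN1 did not pass (-0.57). Of 22 collagens 10 fell and 1 rose, or 11 and 1 adjusted over the list alone. COL12A1 went from 4584 ± 280 to 1395 ± 836 CPM (SD, n = 3; log2 change -1.89, SE 0.31, edgeR paired adjusted p = 0.0138) and COL8A2 fell by 1.49 (SE 0.22), whereas COL13A1, a transmembrane collagen gene, rose by 1.59 (SE 0.14). Of 24 smooth muscle contractile genes 12 fell and 1 rose, or 16 and 1 adjusted over the list alone, with LDB3 and the tropomyosin gene TPM1 falling by 2.67 (SE 0.24) and 0.96 (SE 0.11) and SMTN, the gene of smoothelin, rising by 1.04 (SE 0.15). Camera adjusted p values were 5.12e-05 for the glycoproteins, 0.00143 for the collagens and 3.5e-05 for the contractile genes, and with an estimated correlation the adjusted p was 0.353, 0.354 and 0.353.

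Among 30 matrix proteases and inhibitors 6 rose and 5 fell, or 8 and 7 adjusted over the list alone, and camera did not call the list (adjusted p = 0.772). MMP1 and PLAUR, the urokinase receptor gene, rose by 2.95 and 1.12 (SE 0.25 and 0.11). MMP11 and the inhibitor gene TIMP2 fell by 1.54 (SE 0.19) and 0.57 (SE 0.11), and LOXL3, ADAMTS2 and ADAMTS5 also fell. Without donor 1, ADAMTS5 did not pass. The list's median was -0.01 and its mean 0.18 while camera's direction was up, and its median was 0.10 with totals alone.

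Markers of the 3 classical lineages fell more often than they rose. Of 22 adipogenic markers 13 fell and 2 rose, or 14 and 2 adjusted over the list alone. LEP, the leptin gene, fell by 2.56 (SE 0.46) and the fatty acid receptor gene CD36 by 1.58 (SE 0.24), whereas ADIRF rose by 0.70 (SE 0.15) and PPARG, the master regulator of fat cell formation, by 0.59 (SE 0.17). Of 15 chondrogenic markers 6 fell and 2 rose, or 9 and 2 adjusted over the list alone. ACAN, the gene of the cartilage proteoglycan aggrecan, went from 388 ± 447 to 74.7 ± 92.5 CPM (SD, n = 3; log2 change -2.42, SE 0.17, edgeR paired adjusted p = 0.00384) and COMP fell by 1.36 (SE 0.22). The cartilage transcription factor gene SOX9 rose by 1.06 (SE 0.16), as did PRG4, the gene of lubricin, by 1.25 (SE 0.09), which shares exon sequence with TPR. Of 17 osteogenic markers 7 fell and 3 rose, or 8 and 3 adjusted over the list alone. TNFRSF11B, the gene of osteoprotegerin, fell by 1.99 (SE 0.28) and DLX5 by 0.82 (SE 0.13), and the 3 that rose were PHEX by 1.26 (SE 0.20), BMP6 by 0.83 (SE 0.19) and BMP2 by 2.04. Without donor 1, 7 adipogenic, 4 chondrogenic and 5 osteogenic markers fell, and PPARG, LEP, BMP2 and BMP6 did not pass. Camera gave adjusted p values of 0.171, 0.129 and 0.171 for the adipogenic, chondrogenic and osteogenic lists, and with the donor block the first 2 passed, both at 0.0139, which became an adjusted p = 0.556 with an estimated correlation. In fry with the donor block the adipogenic list had an adjusted p of 0.0464.

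Genes of other developmental pathways fell more often than they rose. Of 30 TGF-beta and BMP pathway genes 13 fell and 3 rose, or 14 and 4 adjusted over the list alone. The activin antagonist gene FST fell by 1.20 (SE 0.12), and TGFBR2, a TGF-beta receptor gene, rose by 0.93 (SE 0.18), with BMP6 and BMP2. Without donor 1, TGFBR2 alone rose and 10 members fell. Of 26 WNT pathway genes 10 fell and 2 rose, or 11 and 2 adjusted over the list alone, the latter being WNT5A, from 290 ± 34.9 to 657 ± 85.7 CPM (SD, n = 3; log2 change 1.18, SE 0.09, edgeR paired adjusted p = 0.00329), and TCF7 at 1.42 (SE 0.14). The receptor genes FZD7 and LGR5 fell by 0.80 (SE 0.12) and 2.42 (SE 0.42). In the IGF axis 9 of 18 genes fell and 2 rose, or 10 and 3 adjusted over the list alone. IGF1R, the receptor gene, fell by 0.90 (SE 0.12) and the binding protein gene IGFBP2 by 0.81 (SE 0.12), whereas STC1 rose by 1.42 (SE 0.14) and IRS1, an adaptor of insulin and IGF receptors, by 0.73 (SE 0.12). Camera called the TGF-beta and BMP list (adjusted p = 0.0136, and adjusted p = 0.353 with an estimated correlation) but not the WNT list (0.193) or the IGF axis (0.0745). The IGF axis passed with the donor block (adjusted p = 0.0267, and adjusted p = 0.556 with an estimated correlation).

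Targets of ATF4, the transcription factor of the amino acid response, fell more often than they rose. Of 25 members of that list 12 fell and 0 rose, or 18 and 0 adjusted over the list alone. The amino acid transporter gene SLC38A2 went from 1341 ± 252 to 609 ± 133 CPM (SD, n = 3; log2 change -1.14, SE 0.19, edgeR paired adjusted p = 0.0127), and ATF4 itself fell by 0.77 (SE 0.15). Of 21 hypoxia targets 6 fell and 1 rose, or 10 and 1 adjusted over the list alone, with PPFIA4 and INSIG2 falling by 0.92 (SE 0.15) and 0.66 (SE 0.11) and the angiogenic factor gene VEGFA rising by 0.54 (SE 0.13). Camera called both lists (adjusted p = 9.35e-08 and 0.00128), with an adjusted p = 0.353 and 0.354 with an estimated correlation. Of 25 cholesterol synthesis genes 7 fell and 1 rose, or 9 and 1 adjusted over the list alone. SREBF2, the transcriptional regulator of the pathway, fell by 0.59 (SE 0.10), and EBP, a sterol isomerase gene, rose by 0.75 (SE 0.10). Without donor 1, 3 fell, HMGCS1 and SREBF2 among them. Camera did not call the cholesterol list (adjusted p = 0.188), nor with an estimated correlation (0.364, or 0.556 with the donor block). Fry gave an adjusted p of 0.00248 with the donor block and 0.115 without it. Glycolysis genes mostly did not pass, with 1 of 22 that rose (PFKP by 0.50, SE 0.10) and 2 that fell (ALDOC by 1.13, SE 0.23, and the glucose transporter gene SLC2A1 by 0.77, SE 0.21), or 1 and 1 adjusted over the list alone (camera adjusted p = 0.678). The glycolysis median was 0.07 and its mean -0.03, with camera's direction up.

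Surface markers of these cells moved in both directions, with 5 of 16 that rose and 3 that fell, or 6 and 3 adjusted over the list alone. ANPEP (CD13) went from 478 ± 142 to 1510 ± 335 CPM (SD, n = 3; log2 change 1.68, SE 0.14, edgeR paired adjusted p = 0.00399) and NT5E (CD73) from 556 ± 107 to 1212 ± 135 CPM (log2 change 1.13, SE 0.14). NGFR, CD9 and CD44 rose by 0.75, 0.58 and 0.43, while ENG (-0.04) and THY1 (-0.15) did not pass. Without donor 1, CD9 and CD44 did not pass either. The collagen-binding integrin genes ITGA11 and ITGA1 fell by 1.25 (SE 0.23) and 0.88 (SE 0.12). ITGA1 shares exon sequence with PELO. Camera did not call the list (direction up, adjusted p = 0.623), whose median and mean of -0.01 were below 0 and whose median became 0.12 with totals alone. Of 13 marrow niche factors 5 fell and 2 rose, or 6 and 2 adjusted over the list alone. The adhesion molecule gene VCAM1 and LEPR, a marker of marrow stroma that shares exons with LEPROT, fell by 2.22 (SE 0.46) and 1.70 (SE 0.19), as did EBF1, CXCL12 and FOXC1, and NES rose by 1.06 (SE 0.10) and EBF3 by 0.49 (SE 0.12; camera adjusted p = 0.772). VCAM1, EBF3, EBF1 and FOXC1 did not pass without donor 1. Of 10 pericyte markers 3 fell and 0 rose, or 4 and 1 adjusted over the list alone: KCNJ8 by 1.05 (SE 0.14), PDGFRB, and TBX18 by 0.57 (camera adjusted p = 0.217). Without donor 1, TBX18 did not pass.

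Markers of blood, endothelial, epithelial and neural cells, which the cultures could also hold, were low. Where tested, their group means reached at most 9.06 CPM (TEK after PDGF-BB), except for CD74 at 16.5 and CD68, a lysosomal protein gene that is not restricted to macrophages, at 111. Of 12 haematopoietic markers 3 rose and 1 fell, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.369). PTPRC (CD45) had 0.463 ± 0.209 CPM in control and 1.03 ± 0.640 CPM after PDGF-BB (SD, n = 3), HLA-DRA rose by 0.91 (SE 0.23) and CD74 by 0.49, and ITGB2, which overlaps an antisense gene, fell by 0.96 (SE 0.17). Of 11 endothelial markers 3 rose and 0 fell, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.126). The 3 that rose were MMRN2 by 0.93 (SE 0.16), PECAM1 by 1.00 (SE 0.23) and ROBO4 by 0.99. Camera called the endothelial list higher without donor 3 (adjusted p = 0.012), but not without donor 1 (0.527) or donor 2 (0.0767). Of 6 epithelial and neural markers 2 rose, over all genes and adjusted over the list alone (camera adjusted p = 0.369), the keratin gene KRT15 by 2.03 (SE 0.27) and the claudin gene CLDN4 by 1.30 (SE 0.30). Without donor 1, whose PDGF-BB library had reads on the most genes, HLA-DRA, KRT15 and the same 3 endothelial markers rose, the endothelial marker SOX18 fell as well, and PTPRC, CD74 and CLDN4 did not pass.

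Interferon-stimulated genes were divided, with 6 of 29 that rose and 8 that fell, or 9 and 13 adjusted over the list alone. The oligoadenylate synthetase genes OAS1 and OAS3 rose by 1.87 (SE 0.25) and 0.99 (SE 0.12), while the interferon signalling gene STAT2 fell by 0.97 (SE 0.15; camera adjusted p = 0.665). Without donor 1, 3 rose (IFI44, OAS1 and OAS3) and 1 fell (STAT2). Of 39 chromatin regulators 9 rose and 6 fell, or 10 and 8 adjusted over the list alone. The maintenance DNA methyltransferase gene DNMT1 rose by 0.80 (SE 0.09) and ASF1B, a histone chaperone gene, by 1.53 (SE 0.18), whereas the deacetylase gene HDAC9 fell by 0.87 (SE 0.15) and ARID5B by 1.57 (SE 0.26). Without donor 1, 5 rose and 2 fell, and ARID5B did not pass. Camera did not call the list (direction up, adjusted p = 0.537), and its median of -0.05 became 0.08 with totals alone.

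**Figure D3:**
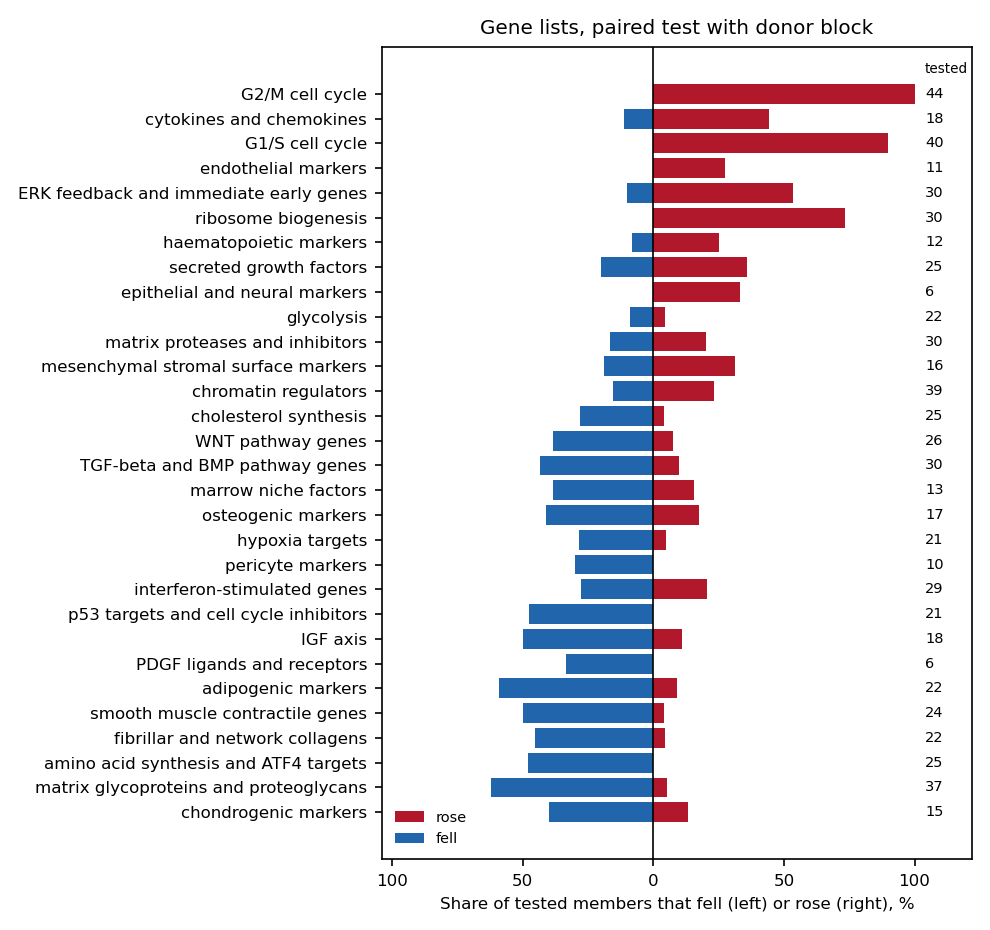
Share of the tested members of each of the 30 gene lists that rose (right) or fell (left) in the paired edgeR test, in percent, ordered by the median log2 change of the list, with the number of members tested beside each bar. The G2/M bar reaches 100% on the right, and the matrix glycoprotein bar is the longest on the left, at 23 of 37.

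In all, camera called 12 of the 30 lists, 5 higher and 7 lower, and 15 with the donor block, 5 higher and 10 lower. Scaled by library totals alone it called 5 higher and 12 lower. With an estimated correlation it called 0, with a smallest adjusted p of 0.353, or of 0.556 with the donor block. Fry called 0 lists without the block, with a smallest adjusted p of 0.0533, and 2 with it.

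Donors also differed from each other. In the paired edgeR model 2898 genes differed among the 3 donors, and DESeq2's likelihood ratio test called 3369. The G2/M list had a median of 3.79 log2 CPM in the control of donor 2, against 2.49 and 2.94 in the controls of donors 1 and 3, and of 4.58, 5.03 and 4.19 after PDGF-BB in donors 1, 2 and 3.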

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

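The tests on reads of otherwise silent genes were chosen after that signal was seen, except the test on markers of other cells, whose bounds were set before its result was known.

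Rows that the comparison did not use were also tested. With the donor block, 72 of the 494 rows without a gene name that had enough counts for edgeR passed, 20 higher and 52 lower after PDGF-BB. Without the block 0 passed. Among named genes the paired test called a larger share, 3777 of 14415. No identity can be given for the 72 rows.

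The PDGF-BB library of donor 1 had reads on 2777 genes that were silent or nearly so in the other 5 libraries (at most 5 reads in all), where the same count ran from 752 to 981 in each of the others. These reads numbered 14309, or 0.0437% of the library, and none of the genes was among those tested. Genomic DNA read evenly along exons would give olfactory receptor genes the same density as other such genes. Their ratio was 0.443 (95% bootstrap interval over genes 0.29 to 0.62), below the 0.8 that it needs. The upper end passes the bound of 0.6 set at first, which was replaced by 0.8 once the ratio was known. Of such genes of at least 500 bases, 47.7% carried a read, against 77.7% expected for reads spread evenly. Both argue against an even background of DNA as the whole of the signal, while uneven DNA was not tested. Blood, endothelial, epithelial or nerve cells in the culture remain open. Of 16 otherwise silent markers of such cells or of pericytes, 11 carried a read, 68.8% (95% exact interval 41.3% to 89.0%). The share was 38.7% over all otherwise silent genes. Over those of at least 500 bases it was 47.7%, which lies within that interval. Across these genes the counts correlated by rank at 0.368 with PDGF-BB replicate 3 and at 0.0909 to 0.138 with the other 4 libraries.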

How the results depend on the processing

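All alternatives to the paired test were chosen after the results were seen, except DESeq2, the fit without the block and leaving out donors, and so was scaling of the lists by totals alone. Without the donor block edgeR called 0 genes and the replicate block raised this to 3777, DESeq2 with the block to 3664 and DESeq2 without it to 1543. It stayed at 0 under other scalings, filters, priors, limma-voom and the 1.5-fold test, and ran from 0 to 475 without single libraries or donors, the 475 without PDGF-BB replicate 2. With the block, 401 genes passed against a 1.5-fold change, and 0 to 4265 without a donor: 2198 without donor 1, 4265 without donor 2 and 0 without donor 3. Each of these fits has 1 residual degree of freedom. Of the 3777 genes, 3368 were also called by DESeq2, 3681 by limma-voom, 3125 with totals alone, 3498 after thinning to the shallowest library and 2061 without donor 1, and in none of these alternatives did a called gene change direction. The other alternatives called 3251 (no filter) to 4147 genes (totals alone).

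For the gene lists, an estimated correlation gave 0 called lists against 12, fry 0, and the donor block with an estimated correlation 0. The count was 12 to 15 without a donor, 12 with RLE factors and 17 with totals alone. Leaving out donor 2 added the PDGF, adipogenic and IGF lists, and leaving out donor 3 added the endothelial list. In camera with the preset correlation, the block changed no list's call other than the adipogenic, chondrogenic and IGF lists. In fry it changed the calls of the cholesterol list (adjusted p from 0.115 to 0.00248) and the adipogenic list (0.257 to 0.0464). Of 117 tested named genes, 115 passed with the block, 114 in DESeq2 with the block and 68 in DESeq2 without it. Without the block 5 of them changed sign when single libraries were left out, with ranges of -0.26 to 0.32 for PDGFRA, -4.85 to 0.89 for PDGFD, -2.00 to 0.13 for CXCL16, -1.73 to 0.17 for CXCL12 and -0.99 to 3.00 for HLA-DRA. None of these passed in any such fit, and the cause was not tested. Genes that differed between donors numbered 2763 to 3369. At these depths 10039 named genes had too few counts to test.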

Other observations

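The tests of lower matrix and contractile genes were chosen after that result was seen, and the tests on other splits, on donor 2 and on symbol families had their bounds set before.

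Some families of genes with a shared symbol changed more often than other genes. Genes were grouped by symbol into 448 families of at least 5 tested genes, and 896 one-sided Fisher's exact tests were run on the paired edgeR calls. In 6 of these tests the family passed adjusted p 0.05. Genes of the large subunit of the mitochondrial ribosome (MRPL) rose in 21 of 48 cases (adjusted p = 2.87e-05), MRPL17 by 0.63 (SE 0.09) and MRPL52 by 0.72 (SE 0.14). All 7 genes of the PSMC group rose (adjusted p = 0.000152), which are ATPases of the proteasome except PSMC3IP, a meiotic recombination gene, as did 9 of 16 of PSMD (adjusted p = 0.00603), mostly further subunits of the proteasome's regulatory particle, with PSMD14 at 0.72 (SE 0.09). The antisense RNAs PSMD5-AS1, which fell, and PSMD6-AS2 were grouped there by symbol. Related families did not pass, with 7 of 30 genes of the small subunit of the mitochondrial ribosome (MRPS) that rose (adjusted p = 0.879) and 5 of 8 of the proteasome core (PSMA, adjusted p = 0.0979). Genes of the CCT chaperonin rose in 7 of 10 cases and nucleoporins in 10 of 20 (both adjusted p = 0.00603), CCT5 by 0.74 (SE 0.10) and NUP205 by 0.62 (SE 0.08). The pseudogenes CCT6P1 and CCT6P3 and the noncoding NUP50-AS1 count among these groups and did not pass. Aldehyde dehydrogenase genes fell in 8 of 14 cases (adjusted p = 0.0117), ALDH4A1 by 0.99 (SE 0.11) and ALDH2 by 0.46 (SE 0.10). The median changes kept their sign under every scaling tried, from 0.27 to 0.40 for MRPL and from -0.41 to -0.27 for the aldehyde dehydrogenases. Members of a family are not independent, so these p values are too small if members move together for other reasons.

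The lower levels of matrix and contractile genes may be a response of the cells to PDGF-BB, as a hypothesis. A few abundant genes with a changed share of the counts would shift these lists through scaling. With totals alone the median of their 83 tested members was -0.58 (95% bootstrap interval over genes -0.80 to -0.44), against -0.71 with TMM. The change of scaling is a nearly constant shift, as the median of all tested genes went from -0.02 with TMM to 0.11. That shift is small beside the fall of these lists, which argues against scaling as the whole of it. Of the 45 members that fell, 43 were also called with totals alone, but they were chosen from the same counts and add no support. The lower depth of the PDGF-BB library of donor 1 is argued against by the median of donors 2 and 3 alone, -0.56 (-0.69 to -0.34). Both intervals resample genes and measure no spread between donors. A change in the rate of division, which was not measured, and a change in the mix of cells were not tested apart from the treatment.

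Changes were smaller in donor 2. Among 1049 genes that moved by more than 2-fold in the same direction in donors 1 and 3, the median change of donor 2 was 0.524 of theirs, and by the same rule it was 1.28 for donor 1 and 0.815 for donor 3. Thinning to equal totals left it at 0.522 (95% bootstrap interval 0.501 to 0.545), which argues against depth. The intervals in this paragraph resample genes, so they measure no spread between donors or cultures. Outside the cell cycle lists, with 1002 of the 1049 genes left, it was 0.507 (0.481 to 0.528). The smaller changes were thus not confined to the listed genes. So few genes were removed that the median could hardly move, and other genes tied to division were not tested. A difference between donors in the response to PDGF-BB may remain, but with 1 culture per donor and condition it cannot be separated from a difference between plates.

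With 3 libraries against 3 there are 10 splits of the 6 libraries, so no count from them can have a share under 0.05. Without the block the real split called 0 genes and the highest of the others 0, so all 10 gave as many. For the lists the real split called 12 and the highest other 13, so 2 of the 10 gave as many. That other split set both libraries of donor 3 and the control of donor 1 against the rest, so it follows donors in large part. Swapping control and PDGF-BB within donors gives 4 arrangements, and with the block the real one called 3777 genes and the highest other 0, so 1 of the 4 gave as many, a number too small for a share under 0.05.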
